A study of Labrus bergylta with 77 samples.

How the data were processed

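Messenger RNA was measured in 77 pools of whole ballan wrasse (Labrus bergylta) larvae. Per the labels' protocols, total RNA was extracted with QIAzol, except at the first stage, BW0, where TRIzol was used, and libraries were made from RNA enriched with oligo(dT) beads. Tank, diet, age, standard length and stage of each pool were taken from the labels.

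The deposited table gives TPM (transcript abundance scaled to a fixed sum per library) per gene for each pool, and every column of the deposited table sums to 1000000. Per the submitters' processing notes, Salmon and edgeR were used. Their versions and options, the role of each tool and the transcriptome are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval can be given. The table holds 29932 genes, of which 29918 carry a LABE identifier and 14 are hand-named immunoglobulin, polymeric immunoglobulin receptor and T-cell receptor sequences. A name of unknown is given to 6058 of them, 80 names are truncated at a colon, and 20.7% of all values are 0. Gene positions were not analysed here.

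The values were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and tested in R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1. Figures were drawn with matplotlib 3.10.9. The plan made before the data were examined assumed read counts and named limma on log2 values as the test for any other unit, so limma was used on the deposited TPM. The diet was given to tanks, so the tank is the replicate. Values were log2(TPM + 1), averaged over the 2 pools of a tank at a stage, which gave 36 tank libraries from 6 tanks at 6 fed stages beside 5 pools of BW0. Genes with at least 1 TPM in at least 3 of these 41 libraries were tested, 22028 in all. The pseudocount of 1 shrinks the differences of genes with low levels.

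One limma fit with an intensity trend held the 13 stage and diet groups. Its contrasts were plankton minus control at each of BW2 to BW7, each stage minus the one before over both diets with equal weight, and the diet difference at BW6 and BW7 minus that at BW2 to BW5, which is called the feeding period contrast because live feed had ended before BW6. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of one contrast. The residual degrees of freedom were 28 and the prior added 3.61. For lymphoid genes, the stage of first rise was the earliest stage with a called increase over BW0 that all later stages kept.

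Before the data were examined, 27 gene lists were fixed: antigen presentation, antioxidant and xenobiotic, B cell and immunoglobulin, cell cycle, cholesterol synthesis, circadian clock, complement and acute phase, erythroid, exocrine pancreas, fatty acid oxidation and PPAR, fatty acid synthesis and LC-PUFA, heat shock and stress, inflammation, interferon and antiviral, intestinal digestion and absorption, keratinocyte and skin, lens crystallin, liver plasma proteins, mucosal barrier and goblet, myeloid and pan-leukocyte, neuronal and glial, photoreceptor, pigment cell, skeletal muscle, skeleton and cartilage, T cell and thymus, and thyroid and growth axis. They matched 1531 genes of the table by name. Among these are the hand-named sequences, which were placed in the T-cell and B-cell lists. After the names of the table were seen, names with more than 20 copies were left out, which removed 104 copies of CD22, 98 of TRIM25 and 22 of GIMAP8. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

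Genes are named by a rule set before their values were seen, apart from the additions given at its end. For a diet comparison it takes up to 6 called genes in each direction with the largest difference, a mean of at least 5 TPM and no overlap between the groups, and for a stage step up to 5. For each list past the camera test it takes the 4 members with the smallest p in the list's direction and 1 called member against it. A fixed set of lymphoid genes is looked up in every comparison. CD3G, Tcra, Tcrd and the hand-named immunoglobulin D sequences were not in the set as planned and were added to it.

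The procedure was tested on simulated data drawn for each gene around 1 mean over all stages, with 1 spread pooled over the 13 groups. For the diet difference at BW4, 81% of genes changed 2-fold and 100% of genes changed 4-fold were called, and 4.23% of the calls were false. For the step from BW4 to BW5 these shares were 89%, 98% and 3.11%, and for the feeding period contrast 86%, 100% and 3.63%. A changed list was found in 1 of 1 cases in each. The simulated noise was drawn for each gene separately, so list members did not vary together as in the real lists. The list simulation therefore cannot show how often camera errs with correlated genes. Changed genes were drawn without those of low or very high level, so their recovery was not tested. In the real data the spread was unequal. Pools of different tanks differed by a root mean square of 0.670 (log2) in plankton at BW2 and 0.374 in control at BW4. The simulation gave every group the same spread, so its share of false calls does not cover groups whose spreads differ.

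The labels give the tank of each pool, so one tank followed over stages pairs its libraries. Deviations from the group means correlated over all tested genes with a median r of 0.009 in 90 pairs of libraries from one tank and -0.002 in 180 pairs from different tanks of a diet, and 7 of the 90 exceeded 0.1. For the step from BW2 to BW3 the pairs of one tank had a median r of 0.15 and a highest of 0.3. Pools of one tank differed by a root mean square of 0.443 on the log2 scale and pools of different tanks by 0.483.

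Alternatives named before the data were examined were median-ratio size factors, no filter, each pool as its own replicate, a fit of the groups of one contrast alone, the tank as replicate block, the fit without 9 pools whose titles are written with a space after BW, and each tank or BW0 pool left out. Added after the data were seen were a pseudocount of 0.1, the fit without 4 doubted pools, the title style as a term, and the sampling day as a term at BW6 and BW7. Also added were the gene lists with size factors, without the doubted pools and with a tank term, and the developmental position at BW2 and with size factors. A pool was doubted when its values correlated best with a group of another stage, or when its mean correlation with its own group stood apart from the others by Dixon's ratio.

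The text reports a part of the genes and lists taken by these rules, and other results of them are not reported here.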

Results

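RNA was measured in 77 pools of whole ballan wrasse larvae from 4 to 80 days post hatch (dph), in a study of how lymphoid organs and mucosal lymphoid tissue form and how early diets affect this. Stages were set by standard length. The 5 BW0 pools came from incubators at 4 dph, before feeding, at a length of 4 mm. From BW2, 3 tanks (B6, B8 and B10) received the control diet of rotifers and Artemia and 3 tanks (B5, B7 and B9) received zooplankton, with 2 pools per tank and stage. Both diets were sampled at 9 dph at BW2. Control and plankton larvae were then sampled at 16 and 18 dph (BW3), 26 and 28 dph (BW4), 36 and 41 dph (BW5), 58 to 59 dph (BW6) and 79 to 80 dph (BW7), when mean lengths reached 27.2 and 27.3 mm. Dry feed was added from 40 dph and was the only feed from 56 dph, so plankton larvae at BW5 had met dry feed and control larvae had not.

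The number of genes with at least 1 TPM was 18720 ± 788 (SD, n = 5 pools) at BW0. At BW2 it was 17495 ± 871 in control pools and 16827 ± 1340 in plankton pools (n = 6 each), the group with the widest range, 14958 to 18957. From BW3 to BW7 the group means lay between 18200 and 19273. The 50 highest genes of a library took 31.0% ± 1.61 of the TPM at BW0, 38.5% ± 3.22 in plankton pools at BW2 and 42.7% in control pools at BW6. The depth behind these values is unknown. Changes below are on the log2(TPM + 1) scale with their standard error, and levels are mean TPM ± SD over 3 tanks per diet or 6 tanks per stage.

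Diet at BW2 was compared to see what the first feeds changed. Plankton larvae had higher levels of IGFBP1 (LABE_00004774), which binds insulin-like growth factors, at 262 ± 116 against 35.5 ± 11.1 TPM (log2 difference 2.86 ± 0.32, adjusted p = 1.56e-07, n = 3 and 3). FBXO32, a ubiquitin ligase of muscle wasting, was higher by 2.40 ± 0.59 (148 ± 22.9 against 29.5 ± 13.3 TPM, adjusted p = 0.00232), klhl38 (LABE_00001609) by 2.57 ± 0.57, and PDK2 (LABE_00036697), an inhibitor of pyruvate dehydrogenase, by 2.40 ± 0.34. Control larvae had higher levels of chac1 (LABE_00013226), which degrades glutathione, at 801 ± 168 against 94.4 ± 11.4 TPM (-3.06 ± 0.23, adjusted p = 2.95e-10). Bco2 (LABE_00037806), a carotenoid-cleaving enzyme, stood at 37.3 ± 5.03 TPM in control and 0.798 ± 0.273 in plankton larvae (-4.39 ± 0.46), and ass1, an enzyme of arginine synthesis, differed by -2.81 ± 0.21. For FBXO32 and chac1 the plankton tanks lay near the unfed BW0 pools and the control tanks lay away from them. FBXO32 was at 105 to 204 TPM in BW0 pools and 130 to 174 TPM in plankton tanks. For chac1 these ranges were 96.0 to 119 and 81.2 to 101 TPM.

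Among the fixed lists at BW2, 51 of 55 cell cycle genes were lower in plankton larvae and none higher (52 lower adjusted over the list alone, median -1.42), among them CDC20 (LABE_00012565) at -1.82 ± 0.18 and mcm5 at -1.66 ± 0.17. The list passed camera at an adjusted p of 8.56e-36 but had an adjusted p = 0.195 with an estimated correlation. Of 29 cholesterol synthesis genes, 21 were lower and 1 higher (23 and 2 adjusted over the list alone). msmo1 was at 27.3 ± 12.2 against 190 ± 33.2 TPM and SQLE at 8.14 ± 4.31 against 51.8 ± 13.8 TPM, while insig1, which restrains the pathway, was higher by 1.03 ± 0.25. In the skeleton and cartilage list 39 of 81 genes were lower and 3 higher (41 and 5 adjusted over the list alone), with Col1a2 (LABE_00025931) at -1.78 ± 0.27 and, against the list, MMP13 (LABE_00011342) at 1.28 ± 0.21. Liver plasma proteins had 22 of 50 genes lower and 3 higher (23 and 4 adjusted over the list alone), with TTR at -1.91 ± 0.25.

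In the other direction at BW2, 27 of 41 lens crystallin genes were higher in plankton larvae and none lower (31 adjusted over the list alone, median 1.08), for example Gamma-crystallin M3 (LABE_00066474) at 6666 ± 636 against 2537 ± 1034 TPM. Circadian clock genes had 20 of 53 members higher and 2 lower (23 and 2 adjusted over the list alone), including nfil3 (LABE_00048119) at 1.93 ± 0.26 and NR1D2 (LABE_00029231) at 1.53 ± 0.25, with TIMELESS against them at -1.02 ± 0.18. Inflammation genes had 15 of 44 members higher (16 adjusted over the list alone), including SOCS3 (LABE_00003548), an inhibitor of cytokine signalling, at 1.45 ± 0.21. With an estimated correlation the adjusted p of the cholesterol, lens, circadian and inflammation lists was 0.452 each, that of the skeleton list 0.513 and that of the liver list 0.916. TM-IgD, listed at 0 TPM in all 3 control tanks, was at 0.955 ± 0.408 TPM in plankton tanks (adjusted p = 0.0169), a call lost when B7, B8 or B10 was left out.

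In total 6420 genes differed at BW2, 2090 higher and 4330 lower in plankton larvae, of which 290 and 941 differed at least 2-fold. The 2 diets did not overlap in 31.6% of genes, where chance gives 10%. Size factors shifted the median of all genes from -0.10 to 0.00 and gave 4221 higher and 3687 lower, and without B8 the count was 3671 (1604 higher and 2067 lower). Of the doubted pools, B5 R3 of the plankton group correlated better with BW0 (mean r 0.9615) than with its own group (0.9239), and B8 R3 of the control group better with BW3 plankton pools (0.9671) than with its own (0.9608). Without the doubted pools 9463 genes differed, and a fit of the BW2 groups alone called 1315 (446 higher and 869 lower), 1283 of them among the 6420.

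At BW3, mid1ip1b (LABE_00018405), a regulator of fatty acid synthesis, stood at 543 ± 121 TPM in plankton and 23.7 ± 9.14 in control larvae (4.46 ± 0.55, adjusted p = 4.11e-05). Also higher were AHSG (LABE_00041427), a liver plasma protein, by 1.49 ± 0.25 and ugt3 (LABE_00025199) by 1.31 ± 0.17. The lipid carriers APOA1 (58.9 ± 18.6 against 224 ± 32.1 TPM, -1.99 ± 0.27) and apoeb (LABE_00076031) (-2.25 ± 0.45) were lower, as was the lipid droplet protein PLIN2 (-1.60 ± 0.28). EPX (LABE_00008768), an eosinophil peroxidase gene, was at 24.4 ± 15.1 against 94.7 ± 26.6 TPM (-2.15 ± 0.40, adjusted p = 0.00759). Of the genes named here, mid1ip1b, ugt3 and APOA1 were called whichever tank was left out, and AHSG, apoeb, PLIN2 and EPX were not called in at least 1 such fit. None of these genes was called in a fit of the BW3 groups alone.

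At BW3, 13 of 27 lists passed camera with the preset correlation and none with an estimated one. Cell cycle (median 0.18, adjusted p of 2.02e-06) and keratinocyte genes (median 0.17, adjusted p of 4.37e-06, 4 higher adjusted over the list alone) were placed above all other genes and neuronal genes below (median -0.19, adjusted p of 2.69e-05), each with an adjusted p = 0.729 with an estimated correlation and no gene called. In the cholesterol list 1 of 29 genes was lower, msmo1 at -1.47 ± 0.34 (adjusted p = 0.0483), and adjusted over the list alone 13 were lower and 1 higher (median -0.45). Antioxidant and xenobiotic genes had 3 of 40 members higher (6 higher and 2 lower adjusted over the list alone), such as Ugt1a1 at 0.86 ± 0.17 and Glutathione S-transferase A (LABE_00034437) at 0.77 ± 0.14. Fatty acid synthesis and LC-PUFA genes had Acsl4 higher by 0.82 ± 0.15 and PLIN2 lower among 51 members (4 higher and 1 lower adjusted over the list alone). With an estimated correlation the adjusted p of these 3 lists lay between 0.729 and 0.778. In total 62 genes differed, 31 higher and 31 lower, and groups did not overlap in 11.6% of genes against 10% by chance. The count fell to 9 without B8, 14 without B6, 31 without B10, 32 without B5 and 36 without B7. Both pools of plankton tank B5, and no others at BW3, have a spaced title, so tank and title style cannot be told apart there. Without the pools with a spaced title 18 genes were higher and 37 lower. With each pool as its own replicate 96 were higher and 123 lower, and with the title style as a further term 52 and 216. A fit of the BW3 groups alone called 1 gene and kept 0 of the 62 calls with limma, where 1416 genes had an unadjusted p under 0.05. The count was 171 without the doubted pools, among them B9 R2 of the plankton group (mean r 0.9558 with its own group and 0.9564 with control pools of BW3).

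At BW4 the digestive enzymes of the exocrine pancreas were higher in plankton larvae. CTRC, a chymotrypsin, stood at 108 ± 9.35 against 17.9 ± 3.19 TPM (2.54 ± 0.27, adjusted p = 1.23e-06, n = 3 and 3), the elastase CELA2A (LABE_00039922) at 1767 ± 107 against 525 ± 60.3 TPM, and the lipase-related gene PNLIPRP1 at 581 ± 53.2 against 167 ± 25.3 TPM. Of 43 genes in the exocrine pancreas list 27 were higher and none lower (29 and 1 adjusted over the list alone, median 1.27), with an adjusted p of 8.18e-72 by camera and an adjusted p = 0.000302 with an estimated correlation. Liver plasma proteins had 6 of 50 genes higher (12 adjusted over the list alone, median 0.38), including APOH (LABE_00029722) at 1.26 ± 0.22 and VTN (LABE_00019653) at 1.18 ± 0.21, with an adjusted p = 0.18 with an estimated correlation. Intestinal genes had 2 of 80 members higher, among them LCT (LABE_00037611) at 1.12 ± 0.26, and 1 lower, FABP6 (LABE_00040749), a bile acid carrier, at -0.84 ± 0.20 (6 higher and 1 lower adjusted over the list alone), with an adjusted p = 0.662 with an estimated correlation.

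Control larvae at BW4 had more chac1 (LABE_00013226), at 1460 ± 172 against 296 ± 67.2 TPM (-2.36 ± 0.23, adjusted p = 2.47e-07). Atf4 (LABE_00090962), a transcription factor of the amino acid and stress response, was at 178 ± 14.2 against 113 ± 12.4 TPM (-0.65 ± 0.15, adjusted p = 0.0283), and Aldh18a1 (LABE_00051286), an enzyme of proline synthesis, and ass1 were lower in plankton larvae by -1.50 ± 0.23 and -1.30 ± 0.21. In the heat shock and stress list 2 of 69 genes were lower and 1 higher (3 and 1 adjusted over the list alone), the higher one being PCK1 (LABE_00058022), a gluconeogenic enzyme, at 1.99 ± 0.39, and the list had an adjusted p = 0.824 with an estimated correlation. In total 147 genes differed, 95 higher and 52 lower, and groups did not overlap in 30.3% of genes. The count was 64 without B8 and without B10, 73 without B6, 83 without B7 and 84 without B5. A fit of the BW4 groups alone gave 1077 (405 higher and 672 lower).

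At BW5 the pancreas list was again higher in plankton larvae, with 6 of 43 genes called and 29 adjusted over the list alone (median 0.75, adjusted p = 0.0243 with an estimated correlation). CTRC had means of 91.9 against 26.1 TPM (1.86 ± 0.27, adjusted p = 0.000278), and the trypsin gene Prss1 was higher by 2.17 ± 0.37. CXCL8 (LABE_00028951), a chemokine that attracts neutrophils, was at 1.53 ± 0.577 in plankton and 37.3 ± 26.8 TPM in control larvae (-3.46 ± 0.34, adjusted p = 4.09e-07), the lowest adjusted p among the genes named at this stage. chac1 (LABE_00013226) was lower by -1.57 ± 0.23, the complement gene c8b by -1.19 ± 0.27 and the antiviral gene IFIT1 (LABE_00057645) by -1.01 ± 0.20. In total 66 genes differed, 35 higher and 31 lower, and groups did not overlap in 14.4% of genes. The count was 22 without B5, 24 without B8, 25 without B10, 26 without B6, 27 without B7 and 211 without B9 (163 higher and 48 lower), and a fit of the BW5 groups alone called 0 genes with limma, where 1842 had an unadjusted p under 0.05.

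At BW6, when both diets had received dry feed alone, Trypsin-3 (Fragment) (LABE_00023352) stood at 880 ± 70.2 in plankton and 171 ± 21.6 TPM in control larvae (2.53 ± 0.24, adjusted p = 1.73e-07). The proteases CTRL, Cpa1 and CPB1 were higher by 2.21 ± 0.27, 2.06 ± 0.25 and 1.96 ± 0.23. The pancreas list had 25 of 43 genes higher and none lower (30 and 1 adjusted over the list alone, median 1.63, adjusted p = 0.0012 with an estimated correlation). Liver plasma proteins had 10 of 50 genes higher (31 higher and 1 lower adjusted over the list alone, median 0.63, adjusted p = 0.0852 with an estimated correlation), including AGXT at 0.92 ± 0.19 and SERPINC1 at 0.88 ± 0.18. Complement genes had C5 (0.95 ± 0.23) and ITIH3 (LABE_00050847) (0.86 ± 0.16) higher among 48 members (7 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation).

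T-cell genes were among those higher in plankton larvae at BW6. The recombinase genes rag1, which assembles antigen receptor genes, and rag2 were at 7.30 ± 2.29 against 3.47 ± 1.62 TPM (0.90 ± 0.21, adjusted p = 0.0283) and 3.85 ± 1.62 against 1.83 ± 0.418 TPM (0.73 ± 0.17, adjusted p = 0.032). The T-cell receptor gene Tcra was at 7.61 ± 2.41 against 3.32 ± 0.653 TPM (0.95 ± 0.21, adjusted p = 0.0174), and the receptor kinase ZAP70 was higher by 0.46 ± 0.11. In all 4 of 34 genes of the list were higher (8 higher and 1 lower adjusted over the list alone, median 0.12, adjusted p = 0.444 with an estimated correlation), and each of these 4 calls was lost in at least 4 of the 6 fits that left out a tank. Myeloid genes had 3 of 46 members lower (adjusted p = 0.915 with an estimated correlation), including CXCR1 (LABE_00021493), a chemokine receptor of neutrophils, at -1.04 ± 0.17, and the chemokine CXCL8 (LABE_00028950) was at 8.01 ± 6.45 against 28.1 ± 4.08 TPM (-1.91 ± 0.34).

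Lower in plankton larvae at BW6 were 7 of 41 lens crystallin genes (27 lower and 1 higher adjusted over the list alone, median -0.99, adjusted p = 0.0909 with an estimated correlation), such as Gamma-crystallin M3 (LABE_00024029) at -1.82 ± 0.35 and CRYBB3 (LABE_00011168) at -1.41 ± 0.26. Cell cycle genes had 2 of 55 members lower, MCM2 (LABE_00061151) and rrm2 (24 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation). Keratinocyte genes had 3 of 54 members lower and 2 higher (5 and 2 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation), including LAMB3, a basement membrane laminin, at -0.74 ± 0.17. In total 177 genes differed, 114 higher and 63 lower, and groups did not overlap in 12.4% of genes. The count was 67 without B8, 110 without B6, 117 without B7 and without B10, 235 without B9 (114 higher and 121 lower, so that the excess of higher genes was lost), 300 without the doubted pools, and 4 in a fit of the BW6 groups alone.

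At BW7, Chia (LABE_00058258), an acidic chitinase, stood at 23.8 ± 0.752 in plankton and 7.56 ± 3.08 TPM in control larvae (1.71 ± 0.26, adjusted p = 0.00164). The haemoglobin genes hbb2 (LABE_00055754) and hba2 (LABE_00055756) were higher by 1.35 ± 0.26 and 1.20 ± 0.24, calls that size factors ended. CXCR1 (LABE_00037607) was at 2.80 ± 0.58 against 1.43 ± 0.455 TPM (0.69 ± 0.13, adjusted p = 0.015), and Tnnt3 (LABE_00002134), a fast muscle troponin, was lower by -1.28 ± 0.23. The erythroid list had 2 of 36 genes higher (4 adjusted over the list alone, median 0.30, adjusted p = 0.142 with an estimated correlation), and the T-cell list had no gene called and 5 of 34 higher adjusted over the list alone (median 0.24, adjusted p = 0.142 with an estimated correlation). The pancreas list had no gene called (median 0.37, adjusted p = 0.612 with an estimated correlation). In total 19 genes differed, 16 higher and 3 lower, and groups did not overlap in 13.5% of genes. The count was 2 without B8, 4 without B5, 6 without B6, 7 without B7 and 35 with size factors, and a fit of the BW7 groups alone called 0 genes with limma, where 1893 had an unadjusted p under 0.05.

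**Figure D1:**
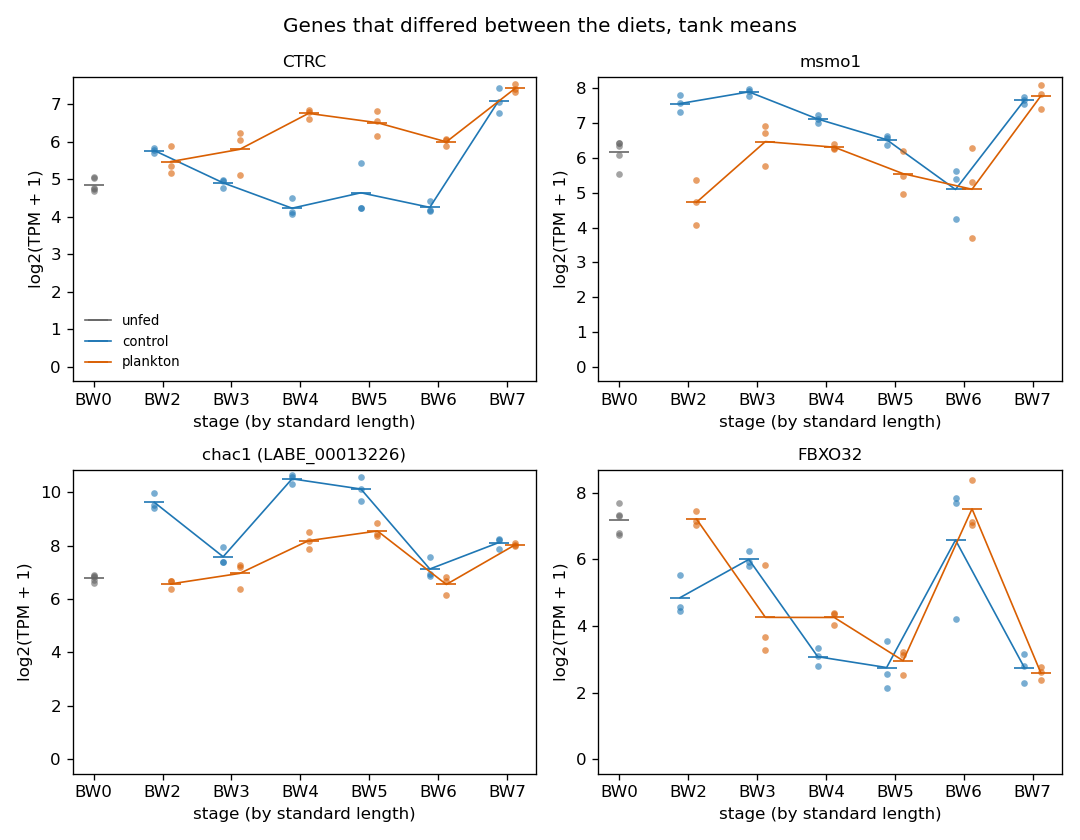
Tank means of CTRC, msmo1, chac1 (LABE_00013226) and FBXO32 on the log2(TPM + 1) axis at each stage, with points for 3 tanks per diet (5 pools at BW0) and lines through the group means. CTRC means were 108 TPM in plankton and 17.9 TPM in control tanks at BW4, and msmo1 means were 27.3 and 190 TPM at BW2.

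The feeding period contrast asked whether the diet difference after live feed (BW6 and BW7) was unlike that before (BW2 to BW5). The diet difference of the cholesterol synthesis genes msmo1, SQLE and FDFT1 rose between the periods by 1.49 ± 0.29 (adjusted p = 0.03), 1.34 ± 0.30 (adjusted p = 0.0484) and 0.85 ± 0.18 (adjusted p = 0.0484). msmo1 was at 190 ± 33.2 TPM in control and 27.3 ± 12.2 in plankton larvae at BW2, and at 202 and 224 TPM at BW7. Over the list 3 of 29 genes were higher and none lower (22 adjusted over the list alone, median 0.83, adjusted p = 0.0852 with an estimated correlation). The median diet difference of the cholesterol list was -1.42 at BW2, -0.45 at BW3, -0.56 at BW4 and -0.30 at BW5. Much of the gap had thus narrowed after BW2, before live feed ended. The diet difference of lens crystallin genes fell, with 3 of 41 members lower (31 adjusted over the list alone, median -0.94, adjusted p = 0.0346 with an estimated correlation), including Beta-crystallin B2 at -1.64 ± 0.36. The median diet difference of the list was 1.08 at BW2, -0.04 at BW3, 0.41 at BW4 and 0.38 at BW5, then -0.99 at BW6 and 0.10 at BW7, so within the later period the negative median was at BW6 alone. Trypsin-3 (Fragment) (LABE_00023352) rose by 1.13 ± 0.21 and LAMB3 fell by 0.66 on the log2 scale. In total 35 genes were called, 22 higher and 13 lower, 2 without B8, 11 without B10, 13 without B7, 14 without B6, 17 without B9 and 53 without B5 (46 higher and 7 lower). Size factors gave 80 and the fit without the doubted pools 152 (111 higher and 41 lower).

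To place the diets along development, each tank was projected on the line between the neighbouring stages, where the earlier stage is 0 and the later stage is 1. At BW3 to BW6 the plankton minus control difference in position was 0.05, -0.01, 0.02 and -0.02, with exact permutation p values of 0.8, 0.7, 1 and 0.8 (two-sided, n = 3 and 3, smallest possible p 0.1).

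The stage steps, over both diets, were compared to follow organ formation. Feed changed along with the stages. Feeding began after BW0, and dry feed was the only feed from 56 dph, shortly before BW6 at 58 to 59 dph. The steps into and out of BW6, like that from BW0 to BW2, therefore cannot tell stage from a change of feed. From BW0 to BW2 the median of all genes shifted by -0.37, and changes are best read against it. lys, a lysozyme gene, rose from 2.71 ± 1.52 (n = 5 pools) to 90.8 ± 28.5 TPM (n = 6 tanks; 4.57 ± 0.26, adjusted p = 3.78e-14) and the pancreatic phospholipase PLA2G1B (LABE_00009956) from 72.3 ± 15.6 to 468 ± 71.1 TPM (2.67 ± 0.22). Green-sensitive opsin (LABE_00050805) fell from 1700 ± 368 to 89.3 ± 47.1 TPM (-4.66 ± 0.14) and APCS (LABE_00032489), a pentraxin, from 104 ± 49.5 to 1.80 ± 3.65 TPM. Another copy, Green-sensitive opsin (LABE_00064357), lay at 782 to 1525 TPM in the BW0 pools and 1005 to 1552 TPM in the BW2 tanks. Of 65 genes of fatty acid oxidation 53 fell and none rose (median -0.74, 53 lower and 1 higher adjusted over the list alone), including CROT at -1.19 ± 0.13, and of 51 genes of fatty acid synthesis 40 fell and none rose (40 adjusted over the list alone, median -0.56). The lens list had 24 of 41 genes higher and 4 lower (24 and 4 adjusted over the list alone, median 0.72). The adjusted p of these 3 lists was 0.655, 0.818 and 0.378 with an estimated correlation.

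Of 13929 genes called from BW0 to BW2, 838 rose and 13091 fell. With size factors the split was 4750 higher and 4820 lower, and the directions of 676 calls were turned. Without the 9 pools with a spaced title, which leaves BW0 pool 3 as the only one of its stage, 1597 genes were called, and with the title style as a term 8389. BW0 was extracted with another reagent than all later stages.

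From BW2 to BW3 the median of all genes shifted by 0.42. Among the genes that rose, Col1a2 (LABE_00025931) went from 37.4 ± 24.9 to 314 ± 104 TPM (3.32 ± 0.19, adjusted p = 2.08e-14, n = 6 tanks each) and the tendon gene TNMD rose by 2.08 ± 0.14. Of 81 skeleton and cartilage genes 66 rose and 2 fell (66 and 2 adjusted over the list alone, median 1.01, adjusted p = 0.768 with an estimated correlation). Intestinal genes had 64 of 80 members higher and 1 lower (65 and 1 adjusted over the list alone, median 1.14), including Apoa4 (LABE_00047832) at 2.72 ± 0.15 and the sterol transporter Npc1l1 at 1.77 ± 0.19. Antigen presentation genes had 35 of 41 members higher and none lower (35 adjusted over the list alone, median 0.75), including the immunoproteasome gene Psmb8 (LABE_00065432) at 2.04 ± 0.16. Both had an adjusted p = 0.984 with an estimated correlation. Lens genes had 24 members lower and 3 higher (24 and 3 adjusted over the list alone, median -1.15, adjusted p = 0.292 with an estimated correlation), with Gamma-crystallin M2 (LABE_00036262) falling from 1867 ± 1080 to 174 ± 82.1 TPM. The inflammation list had 18 of 44 genes higher and 5 lower (17 and 5 adjusted over the list alone, median 0.21), while camera placed it below all other genes (adjusted p = 0.0115, and adjusted p = 0.984 with an estimated correlation). In total 13934 genes rose and 1201 fell. Size factors gave 6577 and 6366, with 1414 calls turned.

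From BW3 to BW4 genes of the skeletal muscle list rose more often than they fell. CASQ1 (LABE_00003820), a calcium store protein of fast muscle, went from 7.88 ± 1.91 to 68.9 ± 7.43 TPM (2.98 ± 0.15, adjusted p = 4.19e-16, n = 6 tanks each) and Parvalbumin alpha from 2234 ± 285 to 8737 ± 1166 TPM (1.96 ± 0.13). Of 92 skeletal muscle genes 52 rose and 6 fell (61 and 7 adjusted over the list alone, median 0.46, adjusted p = 0.0103 with an estimated correlation), with TNNI2 (LABE_00018571) against them at -2.84 ± 0.18. Red-sensitive opsin rose from 0.117 ± 0.136 to 71.0 ± 20.7 TPM (5.91 ± 0.13) while Green-sensitive opsin (LABE_00050805) fell by 3.06 on the log2 scale. Another copy, Green-sensitive opsin (LABE_00064357), lay at 1216 to 2224 TPM in the BW3 tanks and was still at 618 to 992 TPM in the BW4 tanks. Interferon genes had 6 of 43 members higher and 1 lower (6 and 0 adjusted over the list alone, adjusted p = 0.468 with an estimated correlation), with Irf7 at 0.73 ± 0.09. Clock genes had 27 of 53 members lower and 5 higher (28 and 5 adjusted over the list alone, median -0.39, adjusted p = 0.683 with an estimated correlation). In total 1379 genes rose and 5015 fell. The median shift was -0.12 and size factors gave 2498 and 2381.

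From BW4 to BW5 complement genes rose as a group. Of 48 complement and acute phase genes 38 rose and none fell (39 adjusted over the list alone, median 0.87, adjusted p = 0.0443 with an estimated correlation), including the serine protease C1R at 1.72 ± 0.16 and the pore-forming C6 at 1.19 ± 0.13 (n = 6 tanks each). MYLPF (LABE_00039352), a fast myosin light chain, rose from 1724 ± 177 to 13620 ± 1695 TPM, while in the muscle list 52 of 92 genes rose and 28 fell (53 and 29 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). In the erythroid list 18 of 36 genes rose and 7 fell (18 and 7 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), and hbb2 (LABE_00033300) went from 0.639 ± 0.403 to 830 ± 893 TPM, a spread as wide as the mean. Mucosal genes had 11 of 33 members higher and 6 lower (12 and 6 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation), with the mucin MUC5B (LABE_00005601) going from 1.56 ± 0.135 to 6.33 ± 0.946 TPM and MUC2 (LABE_00062112) at -1.20 ± 0.24. Thyroid and growth axis genes had 12 of 44 members higher and 7 lower (12 and 7 adjusted over the list alone), including the thyroid hormone receptor thrb at 1.34 ± 0.14. Its median was -0.04 and its mean 0.12, and camera placed it above all other genes (adjusted p = 0.00209, and adjusted p = 0.243 with an estimated correlation). Cell cycle genes fell in 49 of 55 cases (50 adjusted over the list alone, median -0.70, adjusted p = 0.366 with an estimated correlation). In total 2344 genes rose and 8620 fell. The median shift was -0.22 and size factors gave 4762 and 3362.

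From BW5 to BW6 genes of leukocytes rose together. In the myeloid and pan-leukocyte list 38 of 46 genes rose and none fell (40 adjusted over the list alone, median 0.89, adjusted p = 0.0238 with an estimated correlation), with ptprc, the pan-leukocyte marker CD45, going from 4.42 ± 1.61 to 14.8 ± 1.69 TPM (1.60 ± 0.14, adjusted p = 2.41e-10, n = 6 tanks each). In the T cell and thymus list 26 of 34 rose and 1 fell (26 and 1 adjusted over the list alone, median 0.76, adjusted p = 0.00529 with an estimated correlation). CD3G went from 1.07 ± 0.596 to 9.58 ± 2.88 TPM (2.37 ± 0.14), Tcra from 0.332 ± 0.211 to 5.46 ± 2.83 TPM and CD4 from 0.142 ± 0.0979 to 2.10 ± 0.793 TPM, while Tox fell by 0.43 on the log2 scale. In the B cell and immunoglobulin list 30 of 40 rose and 1 fell (30 and 2 adjusted over the list alone, median 0.62, adjusted p = 0.0231 with an estimated correlation). Many copies of CD40 and several forms each of IgM, IgD and IgT count as separate genes in this list. The secreted form sIgM4 went from 0.817 ± 0.464 to 8.96 ± 2.36 TPM (2.48 ± 0.21) and TM-IgM by 2.66 ± 0.28, while the polymeric immunoglobulin receptor 492pIgR fell by 0.46 on the log2 scale. Inflammation genes had 30 of 44 members higher and 1 lower (30 and 1 adjusted over the list alone, median 0.61, adjusted p = 0.032 with an estimated correlation), including the cytokine il1b (LABE_00049871) at 1.90 ± 0.23.

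Also from BW5 to BW6, the class II invariant chain gene CD74 (LABE_00050764) went from 22.6 ± 14.8 to 192 ± 49.2 TPM (3.24 ± 0.26). Haemoglobin genes moved both ways, with hba going from 4.20 ± 7.60 to 1526 ± 652 TPM and hbb2 (LABE_00055754) from 4915 ± 528 to 137 ± 36.0 TPM (-5.28 ± 0.18). The pancreas list had 27 of 43 genes lower and 9 higher (27 and 9 adjusted over the list alone, median -1.18, adjusted p = 0.582 with an estimated correlation), with PNLIPRP1 going from 282 ± 137 to 42.9 ± 28.9 TPM. Pigment cell genes had 18 of 46 members lower and 1 higher (18 and 0 adjusted over the list alone, median -0.28, adjusted p = 0.675 with an estimated correlation), including the pteridine enzyme pts at -1.58 ± 0.10. In total 3986 genes rose and 5376 fell. The median shift was -0.08 and size factors gave 5330 and 4936.

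**Figure D2:**
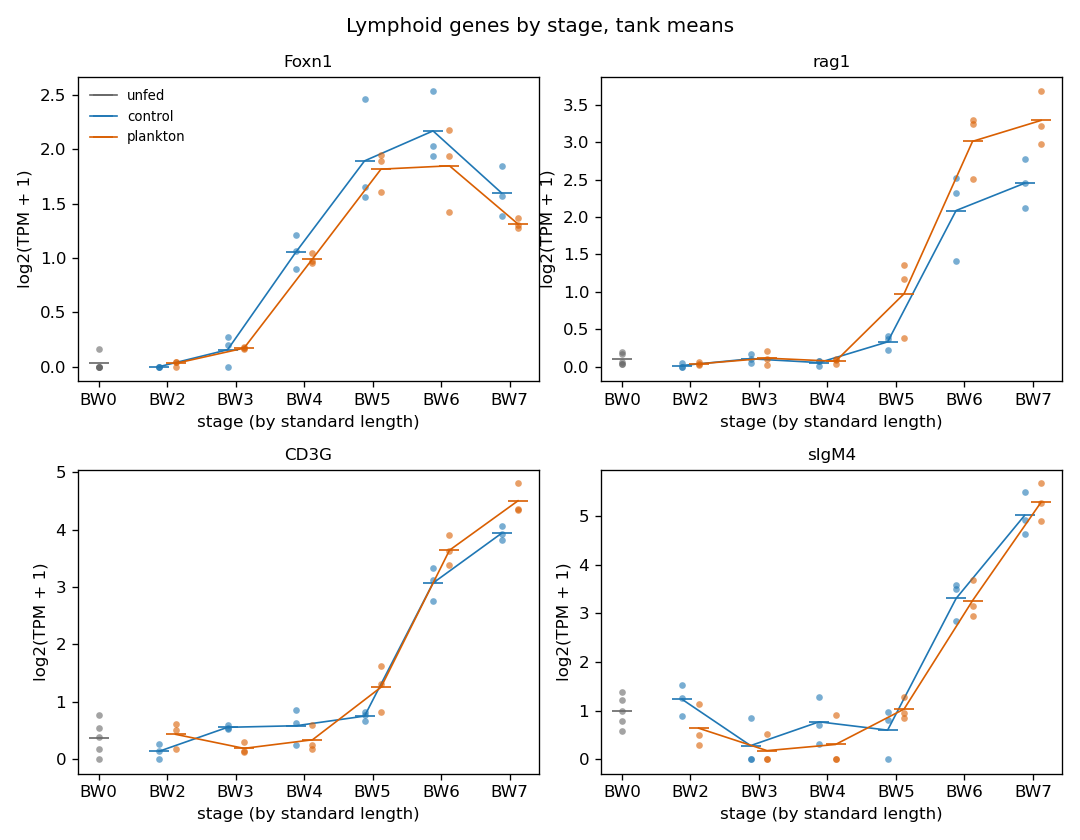
Tank means of Foxn1, rag1, CD3G and sIgM4 on the log2(TPM + 1) axis at each stage, with points for 3 tanks per diet (5 pools at BW0) and lines through the group means. CD3G stood at 1.07 TPM at BW5 and 9.58 TPM at BW6, and sIgM4 at 0.817 and 8.96 TPM.

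From BW6 to BW7 FBXO32 fell from 175 ± 106 to 5.48 ± 1.48 TPM (-4.32 ± 0.42, adjusted p = 1.86e-09, n = 6 tanks each) and klhl38 (LABE_00001609) from 45.6 ± 28.6 to 0.303 ± 0.136 TPM. FBXO32 had been at 3.4 to 10.8 TPM in the BW5 tanks, so its level at BW6 stood above both neighbouring stages. Of 29 cholesterol synthesis genes 24 rose and 3 fell (24 and 3 adjusted over the list alone, median 1.44, adjusted p = 0.117 with an estimated correlation), with msmo1 going from 39.3 ± 23.4 to 213 ± 36.7 TPM. The pancreas list had 28 of 43 genes higher and 3 lower (31 and 3 adjusted over the list alone, median 1.33, adjusted p = 0.117 with an estimated correlation). Cell cycle genes rose in 48 of 55 cases (49 adjusted over the list alone, median 0.57, adjusted p = 0.198 with an estimated correlation). The bone matrix gene bglap (LABE_00062405), osteocalcin, went from 210 ± 78.9 to 971 ± 186 TPM (2.36 ± 0.30). B-cell genes had 20 of 40 members higher and 2 lower (20 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.132 with an estimated correlation), with sIgM4 reaching 35.6 ± 10.2 TPM. T-cell genes had 14 of 34 members higher and 6 lower (14 and 6 adjusted over the list alone, median 0.27, adjusted p = 0.198 with an estimated correlation), with CD3G reaching 18.2 ± 5.08 TPM and Foxn1 falling by -0.57 ± 0.12. Neuronal genes had 43 of 71 members lower and 1 higher (45 and 1 adjusted over the list alone, median -0.48) and photoreceptor genes 33 of 66 lower and none higher (36 adjusted over the list alone, median -0.44), both with an adjusted p = 0.474 with an estimated correlation. In total 2545 genes rose and 5593 fell. The median shift was -0.10 and size factors gave 4731 and 4365.

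To follow the onset of lymphoid tissue, the stage of first lasting rise over BW0 was read for each T- and B-cell gene. The earliest in the T-cell list was CCL25 (LABE_00026307) at BW2. CCL25 (LABE_00000745), CD2 (LABE_00050621), CD247 (LABE_00076159) and Tcrd came at BW3. Foxn1, the transcription factor of thymic epithelium, was at 0.0241 ± 0.0539 TPM at BW0 (n = 5 pools) and rose first at BW4, to 1.09 ± 0.223 in control and 0.99 ± 0.0665 TPM in plankton larvae (n = 3 tanks each). At BW5 rag1, rag2, CD3G, Lck and Tcra followed in the mean of both diets. For rag1 and CD3G this rise was carried mainly by plankton tanks B5 and B7: rag1 was at 1.26 and 1.57 TPM in them and at 0.168 to 0.326 TPM in control tanks, and CD3G at 1.48 and 2.10 against 0.579 to 0.765 TPM. Plankton tank B9, sampled on the same day as B5 and B7, lay near the control tanks, with rag1 at 0.306 and CD3G at 0.771 TPM. CD3G reached 0.709 TPM in a BW0 pool. First rises at BW6 were those of CD4, CCR7, CCR9, FOXP3, Aire and ZAP70. The immunoglobulin genes IgM123, sIgM4, TM-IgM, IgD1234 and TM-IgT rose first at BW6 and IgT1234 at BW7. The polymeric immunoglobulin receptors came earlier, 492pIgR at BW3 and pIgRlike at BW4. Btk and BLNK (LABE_00036152) of the B-cell list also rose first at BW3. Of 34 T-cell genes 25 had such a rise. These were 1 at BW2, 4 at BW3, 2 at BW4, 8 at BW5, 9 at BW6 and 1 at BW7. Of 40 B-cell genes 31 had one. By stage they were 4 at BW2, 7 at BW3, 4 at BW4, 2 at BW5, 13 at BW6 and 1 at BW7. With BW2 in place of BW0, 26 and 33 genes had a rise, and 42 of all 74 genes kept their stage. Of the genes named here, Tcra and IgT1234 then rose first at BW6, ZAP70 and pIgRlike at BW5, and CCL25 (LABE_00026307) at BW4. Tcrd moved from BW3 to BW5. sIgT, at 4.69 ± 3.49 TPM in BW0 pools, had no lasting rise from either baseline. Nor had gata3, TCF7 and the copies of BCL11B and DLL4 in the T-cell list, or the copies of Ebf1 and Prdm1 in the B-cell list. Of these, BCL11B (LABE_00058351) was called above BW0 at BW3 (0.967) and BW4 (0.887). Ebf1 (LABE_00024967) was called above BW0 at the same stages (0.919 and 0.956). Later stages did not keep these increases. The B-cell list holds many copies of CD40, and all its genes with a first rise over BW0 at BW2 were CD40 copies.

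**Figure D3:**
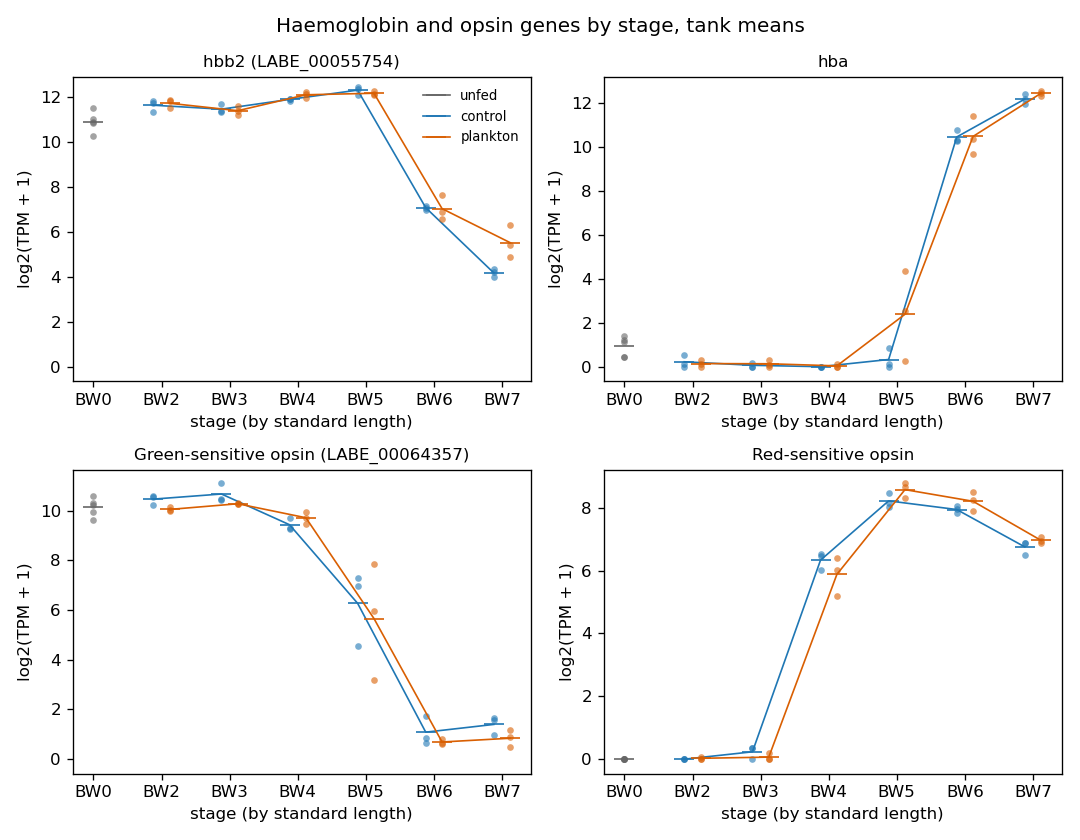
Tank means of hbb2 (LABE_00055754), hba, Green-sensitive opsin (LABE_00064357) and Red-sensitive opsin on the log2(TPM + 1) axis at each stage, with points for 3 tanks per diet (5 pools at BW0) and lines through the group means. hbb2 (LABE_00055754) stood at 4915 TPM at BW5 and 137 TPM at BW6, and hba at 4.20 and 1526 TPM.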

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

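Dixon's ratio was applied to 59 sets of values, each 1 measure or gene in a group of 4 to 10 samples. In 10 of the 59 sets the lowest or highest sample stood apart. The sets share pools, and some are genes with TPM listed in only 1 pool, where that pool stands apart at any level. The count therefore cannot be compared with the chance rate of about 1 in 20, which holds for independent sets without such ties. Plankton pool B5 R3 of BW2 had 32.4% of its TPM in its 50 highest genes, where the nearest pool of its group had 38.1%. Control pool B6 R1 of BW3 had 33.1% (nearest 31.5%) and plankton pool B7 R2 of BW4 had 34.9% (nearest 33.4%). BW0 pool 3 correlated with the other BW0 pools at a mean r of 0.9493, where the nearest had 0.97, and plankton pool B9 R2 of BW3 with its group at 0.9558, where the nearest had 0.9737.

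Among the lymphoid genes, single BW0 pools stood out at low levels. IgD6 was at 1.53 TPM and TM-IgD at 0.266 TPM in pool 3, and Foxn1 at 0.121 TPM in pool 7, each listed at 0 in the other 4 pools. In pool 8, Tcrd was at 0.106 TPM with 0 in the others, and pIgRlike at 0.251 TPM with 0.0497 TPM in the next pool.

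The diet difference of 35 genes was unlike between the feeding periods by the test of that difference, and 8 of them are named by the rule for genes. On the log2 scale the difference moved by 1.49 in msmo1, 1.34 in SQLE, 0.847 in FDFT1 and 1.13 in Trypsin-3 (Fragment) (LABE_00023352), and by -0.656 in LAMB3, -1.50 in cryaa (LABE_00078757), -0.929 in Crybb3 (LABE_00016049) and -1.64 in Beta-crystallin B2. Each of these calls was lost in at least 1 fit that left out a tank.

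Of the tests below, those of the title style, the scaling, the reading of the reagent and both tests of the pancreas list were chosen after the result was seen, and so was the position at BW2 as an analysis. From BW0 to BW2 the median of all genes fell by 0.37 on the log2 scale, and from BW2 to BW3 it rose by 0.42. Against a few high genes as the cause of the fall, the median was still -0.338 without the 50 genes of highest mean. Against the title style as the cause of the rise, it was 0.485 without the pools with a spaced title. The rise itself, 0.418, lies between stages extracted with one reagent, so the BW0 reagent does not enter it by design. For the fall the title style stays open. In the 3 BW2 tanks that hold both styles, genes lower at BW2 were higher in the spaced-title pool. The mean was 0.457 (0.939 in B5, 0.265 in B8 and 0.168 in B10), 79.9% of their median fall of -0.572. This share rests mostly on B5, whose spaced-title pool B5 R3 is doubted, as is B8 R3. The genes were chosen from these libraries as higher at BW0, where most titles are spaced. That choice favours genes higher in spaced-title pools. Among the BW0 pools, 4 of 5 have spaced titles, and these genes were higher by 0.495 in them than in the other pool. That other pool, BW0 pool 3, is doubted and correlated best with BW2 control pools (mean r 0.9543, and 0.9493 with its own group). With 1 such pool, title style cannot be told from a trait of the pool itself. With each pool as its own replicate, the median change of all genes was -0.373, and -0.245 with the title style as a further term. A difference tied to the title style may therefore account for part of the fall, and how large a part stays open. The labels do not say what the title style means. Reagent and age stay open too, since BW0 alone had its reagent.

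Against the title style as the cause of the diet difference at BW2, 6365 of the 6420 called genes kept their call and direction in a fit with each pool as its own replicate and the style as a term. Pools as replicates alone called 8562 genes and kept 6396 of the calls, so the term itself took few of them, and the fit of tanks without the pools with a spaced title kept 6059. Against scaling as the cause, 5513 kept them with size factors. On the axis from BW0 to BW3 the plankton tanks lay at 0.0751 ± 0.07 (SD) and the control tanks at 0.467 ± 0.14, a difference of -0.392 (exact permutation p = 0.1, the smallest possible with n = 3 and 3), with 3 of 3 plankton tanks below each control tank. A later developmental stage of control larvae at 9 dph may underlie part of the difference. The axis starts at unfed larvae and ends at fed ones, so it cannot tell developmental stage from feeding state. Slower growth on the plankton diet and an effect of feed composition stay open and were not told apart by these tests.

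The pancreas list was higher in plankton larvae at BW4 to BW6. Against the greater age of plankton larvae as the whole cause, its median was 1.63 at BW6, where both diets were sampled on the same days. Against a larger share of gut and liver tissue, the diet difference of the list was compared with that of the mean of the liver and intestine lists. It was larger by 0.754 ± 0.102 (SE) at BW4 and by 0.789 ± 0.253 at BW6. Neither test can address a larger share of pancreas tissue in whole larvae, which stays open. The diet, the tanks and the amount of food in the gut at sampling stay open as candidate explanations.

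With 3 tanks per diet there are 10 splits of the 6 tanks, too few for a share under 0.05. The real split and the highest other called 6420 and 1257 genes at BW2, 62 and 1 at BW3, 147 and 0 at BW4 (limma, where 1490 genes of the real split had an unadjusted p under 0.05), 19 and 3 at BW7, and 35 and 13 for the feeding period, so that 1 of 10 splits reached the real count. At BW5 and BW6 2 of 10 did: the split of B5, B7 and B10 from the others called 579 genes at BW5, where the diets called 66, and the split of B5, B6 and B7 from the others called 517 at BW6, where the diets called 177. These point to a structure of the samples beside diet. At BW5, as read after the split was seen, the tanks also part by developmental position: B5, B7 and B10 lay at 0.555 to 0.63 on the axis from BW4 to BW6, and B6, B8 and B9 at 0.38 to 0.454. At BW6, B9 and B10 were sampled a day later than the other tanks, and with the sampling day as a term 196 genes differed by diet.

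For the stage steps 100 splits were drawn, and 1 of 100, the real one, reached the real count in each step, so a chance division of the libraries taken without regard to tanks was excluded. The highest other counts were 12482 from BW0 to BW2, 14437 from BW2 to BW3, 2654 from BW3 to BW4, 5576 from BW4 to BW5, 5563 from BW5 to BW6 and 4392 from BW6 to BW7. From BW2 to BW3 onwards only 12, 19, 15, 14 and 15 of the splits part as many tank pairs, too few for a share under 0.05, and the highest other counts among them were 13528, 2441, 5576, 5563 and 2343.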

How the results depend on the processing

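The counts of genes for diet rest on 3 tanks per diet. Causes of the changes below were not tested, except that fits leaving out tanks hold fewer samples. Size factors gave 35 genes for diet at BW7, 80 for the feeding period and 9 gene lists from BW0 to BW2. No filter gave 55 and 57 for the same diet results. Each pool as its own replicate gave 219, 336, 187, 417 and 46 genes at BW3 to BW7 and 285 for the feeding period, and with the title style as a further term 268, 459, 232, 558, 50 and 502, and 8389 from BW0 to BW2. Fits of the contrast's groups alone gave 1315, 1, 1077, 0, 4 and 0 genes at BW2 to BW7 with limma, the zeros beside 1842 (BW5) and 1893 (BW7) genes at an unadjusted p under 0.05. Without the 9 pools with a spaced title there were 12 genes at BW7, 91 for the feeding period and 1597 from BW0 to BW2, where 1 BW0 pool is left and is assumed to vary like the other groups. A pseudocount of 0.1 gave 117 at BW6, 9 at BW7 and 13 for the feeding period. Without the doubted pools there were 171 genes at BW3, 103 at BW5, 300 at BW6 and 152 for the feeding period. The sampling day as a term gave 196 genes at BW6 and 24 at BW7. With an estimated correlation 0, 0, 1, 1, 1 and 0 lists passed at BW2 to BW7, 0, 0, 1, 1, 4 and 0 in the 6 stage steps and 1 for the feeding period, against 8, 13, 12, 13, 12 and 12, then 15, 7, 14, 17, 14 and 16, and 11 with the preset one. The plankton minus control difference in position at BW2 was -0.27 over the 2000 genes with the largest difference.

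Fits leaving out 1 tank gave 3671 to 6635 genes for diet at BW2, 9 to 78 at BW3, 64 to 143 at BW4, 22 to 211 at BW5, 67 to 235 at BW6, 2 to 28 at BW7 and 2 to 53 for the feeding period. The steps gave 12304 to 14889 (BW0 to BW2, BW0 pools included), 13417 to 14656, 4667 to 5040, 8768 to 9685, 7296 to 8918 and 6075 to 7571. The tank as replicate block (consensus correlation 0.0364 for the diets) gave 6412, 61, 146, 66, 183 and 19 genes at BW2 to BW7, 15034, 6253, 10820, 9168 and 8023 in the steps from BW2 onwards and 32 for the feeding period. For the step from BW0 to BW2 alone, no paired analysis was possible because the BW0 pools did not come from the tanks of BW2. Over 1119 results of named genes and all alternatives, 16291 of 17341 values stayed on their side of the threshold, 768 lost their call, 279 gained one and 3 turned: Crystallin J1C (LABE_00003821) from BW0 to BW2 (0.003246) and nccrp1 from BW4 to BW5 (0.04027) with size factors, and IgD6 from BW0 to BW2 (-0.02534) without the pools with a spaced title. The planned Wald test on counts and the planned voom weights were not run, since both need counts.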

Other observations

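A pair of haemoglobin genes moved in opposite directions between BW5 and BW6 in both diets. hbb2 (LABE_00055754) stood at 2021 ± 613 TPM at BW0 (SD, n = 5 pools) and at 5162 ± 653 in control and 4668 ± 297 TPM in plankton tanks at BW5 (n = 3 each), and at 135 ± 8.37 and 138 ± 56.3 TPM at BW6. hba went from 0.302 and 8.10 TPM at BW5 to 1434 ± 307 and 1619 ± 972 TPM at BW6 and 4722 ± 749 and 5655 ± 425 TPM at BW7. In plankton tanks B5 and B7 hba was already at 4.84 and 19.2 TPM at BW5. In both diets hbb2 (LABE_00033300) had risen a step earlier, from means of 0.31 TPM in control and 0.969 TPM in plankton tanks at BW4 to 470.1 and 1189 TPM at BW5. Among visual pigments, Green-sensitive opsin (LABE_00064357) was at 1154 ± 282 TPM at BW0 and 1.24 and 0.618 TPM at BW6, and Red-sensitive opsin was at 80.6 ± 14.1 and 61.5 ± 24.4 TPM at BW4.

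L-rhamnose-binding lectin CSL2 (LABE_00059110), trp3 and ectD were lower in plankton larvae at BW3 and higher at BW6. CSL2 was at 16.6 ± 16.0 against 126 ± 41.9 TPM in control larvae at BW3 (-3.52 ± 0.74, adjusted p = 0.0228) and at 202 ± 27.4 against 15.8 ± 7.93 TPM at BW6 (3.57 ± 0.74, adjusted p = 0.00906). The change between these 2 stages was not tested by itself.

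chac1 (LABE_00013226) was lower in 3 of 3 plankton tanks than in each control tank at BW2 to BW6. Its control means were 801, 1460 and 1150 TPM at BW2, BW4 and BW5, against 94.4, 296 and 379 TPM. The means lay closer at BW3 (195 against 128 TPM) and BW6 (142 against 94.4 TPM), where it was not called, and at BW7 (279 against 262 TPM).

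Ladderlectin (LABE_00063690) went from 1.41 TPM at BW0 to 1604 ± 3.43 in control and 2893 ± 166 TPM in plankton tanks at BW7. Type-4 ice-structuring protein LS-12 (LABE_00037098) went the other way, from 7180 and 8177 TPM at BW3 to 2.47 and 38.0 TPM at BW7.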
